A study of Mus musculus with 10 samples.

How the data were processed

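Total RNA from complete colon tissue of 10 C57BL/6 mouse samples was measured on 10 single-colour Clariom S Mouse arrays, a gene-level expression array. Per the labels' protocols, colitis was induced with 3% dextran sulfate sodium (DSS) in the drinking water together with an anti-PD1 antibody given intraperitoneally, and part of the mice also received donor cells treated by ECP. ECP stands for extracorporeal photopheresis, in which leukocytes are exposed to a photosensitiser and ultraviolet A light outside the body. Tissue was homogenised in lysis buffer, RNA was isolated with the miRNeasy kit, and biotin-labelled cDNA was made with the GeneChip WT PLUS reagents, per the labels' protocols.

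The deposited values were log2 probe set intensities, made by the authors with oligo and RMA, per the submitters' processing notes. RMA corrects the background, normalises probe intensities across arrays by quantiles and summarises the probes of a probe set by median polish. The versions and options used are not given in the sources used here, and no detection calls were analysed here. The table held 22203 probe sets on 10 arrays. Values lay between 2.81 and 13.6, and array medians between 6.94 and 6.98. Because RMA forces the arrays to a common distribution, a change shared by most genes would not be seen. For arrays, the number of arrays per group limits the precision.

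Probe sets were named through the annotation of the array platform, whose gene identifiers were looked up in a RefSeq gene table. All 19572 probe sets with a gene symbol matched it and had 1 symbol each, 0 symbols needed updating, and 2631 probe sets were unnamed here. Where a gene had several probe sets, the one with the highest mean over all arrays was used, which left 19505 genes. This choice concerned 55 genes, of which 18 had probe sets with differences of opposite sign. No gene picked by the naming rule given below was among the 55. Other genes named in the report were not part of this count. No genome build is named in the sources, and no coordinates are given. One of the fixed genes has no named probe set here and is not analysed.

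Groups were taken from the sample titles, with 5 ECP arrays and 5 control arrays, and the replicate numbers came from the same titles. The labels do not state that each array is a separate mouse, so p-values measure the spread between these samples. The labels and files give no batch, date or sex. Pairwise correlations between arrays ran from 0.976 to 0.995 and no pair of arrays was identical.

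Genes were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided, no covariate, no filter on dim genes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are given as ECP minus control on the log2 scale. Gene lists, 49 in number with 771 different genes of which 700 were measured, were fixed from textbook knowledge of colon, immune and stromal cells. Each list was tested with limma's fry, which asks whether its members move on balance in one direction and does not compare the list with other genes, and p-values were adjusted over the 49 lists. A list's level on an array is the mean log2 value of its measured members. Differences in list level were also given an exact permutation p over the 252 splits of the 10 arrays, of which the smallest possible value is 0.00794. Adjusted over 49 lists this smallest value becomes 0.389 for a single list, so that test could not pass the threshold for 1 list alone. Camera, which compares a list with the other genes, was run as an alternative, with a preset correlation of 0.01 and with an estimated correlation. Principal components were computed from centred log2 values, and the first 4 were tested by exact permutation.

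The groups, tests, lists, the alternatives listed below and the rule for naming genes were set before the data were examined. The rule names, in each direction, the 10 genes with the largest change past the threshold, filled to 10 with the smallest unadjusted p where fewer pass, a fixed set of cytokine, mucosal and adipokine genes, and up to 4 members with the smallest p in each list that is described. The 18 lists described singly were picked after the data were examined, as were 3 alternatives on pancreatic transcripts, the pancreatic acinar list, and the division of the proliferation list into mitosis and DNA replication members. The acinar list of 15 genes was put together after its genes were seen to vary between arrays, and 3 further acinar genes (Cela1, Sycn and Spink1) were left off after their values had been seen. Loadings of the components and list levels of single arrays were looked at before these choices.

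Alternatives set beforehand were median centring, renewed quantile normalisation, leaving out the lowest quartile of genes by mean level or all genes below the median, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust options, array weights, the replicate number as a block, smooth muscle or B cell level as a covariate, each array left out in turn, other set tests, and components of genes scaled to unit variance. The gene and list tests were tested on simulated data, with independent noise for each of the 19505 genes and 200 changed genes in each of 10 simulations. Of genes changed by 0.5 on the log2 scale 69.4% were called, of those changed by 1 97.8%, and 4.38% of all calls were false. The changed genes were spread evenly over shifts of 0.5, 1, 1.5 and 2, and the larger shifts ease the adjusted threshold for the smaller ones. The 69.4% therefore holds only for such a mixture, and an absence of calls in the real data does not exclude changes of 0.5. A list shifted by -0.3 was called in 10 of 10 simulations. The simulation held no correlation between genes, so it does not show how fry behaves on correlated lists. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.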

Results

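Colon tissue of mice with colitis from DSS, a detergent-like polysaccharide that injures the colonic epithelium, combined with an antibody against the checkpoint receptor PD1 was profiled on 10 arrays. In 5 samples the mice had also received ECP-treated donor cells (ECP arrays), and 5 samples came from mice with colitis alone (control arrays). Values are log2 RMA intensities of 19505 genes, and errors are SD over the 5 arrays of a group unless stated. The design has 1 comparison, which addresses what transfer of ECP-treated cells changed in the colitic colon.

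Proliferation genes, a list of mitotic kinases, spindle proteins and DNA replication factors, fell in the ECP arrays. Their mean level was 8.06 ± 0.08 (SD, n = 5) in the ECP arrays and 8.40 ± 0.12 (SD, n = 5) in the control arrays, a difference of -0.34 with SE 0.06. Of 22 measured members 19 were lower and 3 were higher, and 16 were lower past the threshold when adjusted over the list alone, against 0 when adjusted over all genes. Cdc20, an activator of the anaphase-promoting complex, differed by -0.60 (SE 0.10), the spindle checkpoint kinase Bub1 by -0.58 (SE 0.10), the kinetochore protein Cenpf by -0.58 (SE 0.10) and the mitotic kinase Aurka by -0.46 (SE 0.08). The list passed limma's fry test (adjusted p = 0.0220 over 49 lists). Camera, which compares the list with the other genes, did not call it with an estimated correlation between genes (adjusted p = 0.0822). All 5 ECP arrays lay below all 5 control arrays (exact permutation p = 0.00794, two-sided, the smallest that 252 splits can give).

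Pancreatic acinar transcripts, which code for digestive enzymes, were high in control replicates 1 and 4 and slightly raised in control replicate 5. The mean level of 15 acinar genes was 10.2 in control replicate 1, 12.1 in control replicate 4 and 6.27 in control replicate 5, against 5.54 and 5.41 in control replicates 2 and 3 and 5.33 to 5.48 in the ECP arrays. This gene list was assembled after the values were seen. The proliferation call ended without control replicates 1 and 4, an alternative chosen after seeing the data (mean difference -0.28, fry adjusted p = 0.105), without control replicates 1, 4 and 5 (-0.25, 0.687), and with the acinar level (-0.26, 0.0581), the smooth muscle level (-0.31, 0.116) or the B cell level (-0.32, 0.0527) as a covariate. Leaving out 1 array kept the call without ECP replicate 4 (adjusted p = 0.0195) or control replicate 3 (0.00474) and ended it for each of the other 8 arrays (0.0517 to 0.117), with mean differences of -0.38 to -0.30 over all 10.

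**Figure D1:**
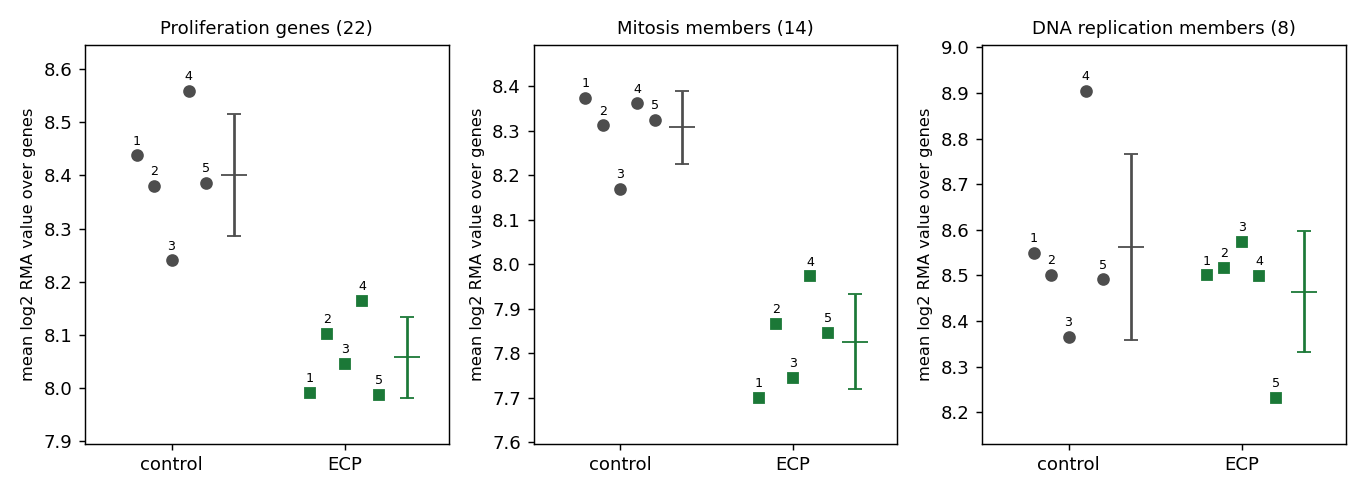
Mean log2 RMA value per array (vertical axes, each with its own range not starting at 0) over 22 proliferation genes, their 14 mitosis members and their 8 DNA replication members, in control arrays (grey circles) and ECP arrays (green squares); numbers are replicate numbers, and horizontal marks with bars are mean ± SD (n = 5). The division into mitosis and replication members was made after the values were seen; mitosis members lay at 8.31 in the controls and 7.83 in the ECP arrays, and replication members at 8.56 and 8.46.

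No single gene passed the threshold. With limma, 0 of 19505 genes had an adjusted p under 0.05, and 991 had an unadjusted p under 0.05 (450 higher and 541 lower in the ECP arrays), where 975 are expected by chance. The cyclin gene Ccna2, which acts in S phase and mitosis, came closest, with a difference of -0.58 (SE 0.07) and an adjusted p of 0.0686. The other genes with the smallest p among those lower in the ECP arrays were Cip2a, H2bc15, Neil3, Melk, Dlgap5, Cenpf, Cdc20, Bub1 and H2bc7, each with an adjusted p of 0.106 and differences from -0.60 for Cdc20 to -0.36 for H2bc15. Several of these code for proteins of the mitotic spindle or its checkpoint, and H2bc15 and H2bc7 code for histone H2B. Among genes higher in the ECP arrays, the interferon-induced gene Ifit1 had a level of 7.51 ± 0.19 against 6.87 ± 0.13 in controls, a difference of 0.64 (SE 0.10, limma adjusted p = 0.106). The macrophage elastase gene Mmp12 differed by 1.03 (SE 0.23, adjusted p = 0.244), and the growth factor gene Pdgfc by 0.44 (SE 0.09, adjusted p = 0.176). Nkain1, Ncam2, Map7d2, Slc46a3, Ptpro, Trappc3l and Hcrtr2 completed this set, with differences of 0.38 for Trappc3l to 0.73 for Nkain1 and adjusted p-values of 0.106 to 0.246. Groups did not overlap for 238 genes (1.22%, against 0.794% by chance). The count of 0 became 7 when genes below the median level were left out (Ccna2, Cip2a, Dlgap5, H2bc15, H2bc7, Neil3 and Ifit1) and 1 when the lowest quartile was left out or trend and robust options were used (Ccna2 in both) or without control replicate 3 (Cenpf).

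Interferon-related lists did not pass the test. Of 20 measured type I interferon response genes 18 were higher in the ECP arrays and 2 lower, with a mean difference of 0.23 (SE 0.12, fry adjusted p = 0.885), or 0.14 without ECP replicate 1. Ifit1 was its 1 member past the threshold when adjusted over the list alone. Ifit3, another interferon-induced gene, differed by 0.43 (SE 0.13), the transcription factor gene Irf7 by 0.44 (SE 0.15) and the mitochondrial kinase gene Cmpk2 by 0.37 (SE 0.13). The 17 interferon-gamma response genes showed a mean difference of 0.08 (SE 0.30, adjusted p = 1.000), with Irf1 at -0.13 and the tryptophan-degrading enzyme gene Ido1 at 0.22, or 0.11 without ECP replicate 1 or control replicate 1 and 0.14 without control replicate 3. Without ECP replicate 1, control replicate 3 or control replicate 5 this mean turned negative, to -0.06 without ECP replicate 1.

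Cytokine and chemokine lists did not pass the test. Of 19 inflammatory cytokine genes 12 were higher and 7 lower in the ECP arrays (mean difference 0.15, SE 0.13, fry adjusted p = 0.923), and of 24 chemokine genes 18 were higher and 6 lower (0.15, SE 0.22, adjusted p = 0.915). Without control replicate 5 these means were 0.05 and 0.03, and without control replicate 4 they were 0.23 and 0.33. Il1b was at 9.51 ± 0.34 in the ECP arrays and 8.89 ± 1.03 in the controls, Il6 at 5.86 ± 0.37 and 5.48 ± 0.76, and Tnf at 7.31 ± 0.29 and 6.81 ± 0.70. Ifng was at 5.40 ± 0.21 and 5.18 ± 0.16, Il17a at 6.88 ± 0.16 and 6.69 ± 0.14, and the anti-inflammatory cytokine gene Il10 at 5.42 ± 0.21 and 5.15 ± 0.14. Il23a differed by 0.31 (SE 0.13) and Il19 by -0.12 (SE 0.06). The chemokine gene Ccl3 differed by 1.04 (SE 0.52), Ccl22 by 0.30 (SE 0.19) and Cxcl9 by 0.28 (SE 0.43). Without control replicate 5 the differences were 0.23 for Il1b, 0.14 for Il6 and 0.01 for Cxcl9, and without ECP replicate 1 that of Ccl22 was 0.12. The Tnf difference was 0.50 with all arrays and 0.31 without control replicate 3. Adjusted p-values of these genes were 0.937 or higher (limma).

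Markers of immune cells gave no list past the threshold either. All 11 measured B cell markers were lower in the ECP arrays (mean difference -0.32, SE 0.55, fry adjusted p = 0.923), with Cd79a, a part of the B cell receptor, at -0.57 (SE 0.55) and the B cell kinase gene Blk at -0.48 (SE 0.37). This difference lay in control replicate 4, whose B cell level was 8.49 against 5.90 to 6.03 in the other controls, and without that array it was 0.18, with Cd79a at 0.02 and Blk at -0.07. Control replicate 4 is also the array with the highest acinar level. T cell and NK cell markers had a mean difference of -0.09 (SE 0.21, adjusted p = 1.000), with the T cell kinase gene Zap70 at -0.22 and the NK receptor gene Ncr1 at 0.16. Without control replicate 4 the list was at 0.11 and Zap70 at -0.13, and Ncr1 ranged from 0.08 without ECP replicate 1 to 0.26 without ECP replicate 2. Neutrophil markers had -0.06 (SE 0.34), with the granule protein genes Camp at -0.21 and Ltf at -0.17, and turned to 0.24 without control replicate 4 and 0.00 without ECP replicate 2. Camp was at -0.32 without control replicate 2, and Ltf at -0.07 without control replicate 4. S100a8, a neutrophil calcium-binding protein gene, was at 7.67 ± 0.65 in the ECP arrays and 7.76 ± 1.65 in the controls, and this difference of -0.09 turned positive without ECP replicate 2 or 3 or control replicate 1 or 4, to 0.41 at most. Monocyte and macrophage markers had 0.08 (SE 0.25), with Adgre1 at 0.39 and the mannose receptor gene Mrc1 at 0.41 (both 0.20 without control replicate 1), and regulatory T cell and tolerance genes 0.03 (SE 0.14), with the ectoenzyme gene Nt5e at -0.42 and Il10 at 0.27. Both of these means turned negative without ECP replicate 1, control replicate 1 or control replicate 5, to -0.06 and -0.03 at the lowest. Cd274, which codes for the PD1 ligand PD-L1, was at 8.02 ± 0.19 and 7.87 ± 0.55. This difference of 0.15 ranged from 0.02 without control replicate 5 to 0.36 without control replicate 4.

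The 5 epithelial lists described here showed mean differences of 0.12 or smaller. Goblet cell and mucus genes had a mean difference of 0.05 (SE 0.10), with 14 of 16 members higher, and the main colonic mucin gene Muc2 was at 13.50 ± 0.06 in the ECP arrays and 13.46 ± 0.13 in the controls. The membrane mucin genes Muc13 and Muc4 differed by 0.07 and 0.12. Without control replicate 4, the goblet list was at -0.04, Muc2 at -0.02 and Muc4 at -0.01. Colonocyte absorptive genes had 0.12 (SE 0.10), with the protocadherin gene Cdhr5 at 0.13 and the meprin gene Mep1a at 0.32, and was at 0.03 without control replicate 4, with Mep1a at 0.20. Stem and crypt base genes had 0.08 (SE 0.04), with the stem cell marker Lgr5 at 0.23 and Cdca7 at 0.27. Epithelial repair and regeneration genes had 0.08 (SE 0.05), with Krt7 at 0.23 and the matrilysin gene Mmp7 at 0.55. Antimicrobial and acute epithelial response genes had 0.03 (SE 0.17), and turned to -0.07 without control replicate 3 or 5. In that list, the antimicrobial lectin genes Reg3g and Reg3b differed by 0.60 (SE 0.28) and 0.35 (SE 0.17), and Lcn2 by 0.30 (SE 0.52), or -0.10 without control replicate 5. Without control replicate 3, Reg3g was at 0.33 and Reg3b at 0.19. Reg3a, named after its values were seen, ran the other way at -1.44 (SE 0.81), with levels of 7.51 and 9.33 in control replicates 1 and 4, which also had the highest acinar levels. Of these 5 lists the smallest fry adjusted p was 0.885.

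Stromal and fat cell lists were higher in the ECP arrays without passing the test. Smooth muscle genes had a mean difference of 0.26 (SE 0.17, 14 of 15 higher), or 0.13 without control replicate 1, with the contractile actin gene Actg2 at 0.49 (0.30 without control replicate 1) and the muscle coactivator gene Myocd at 0.33. The smooth muscle level was lowest in control replicates 1 and 4 (8.61 and 8.95), which also had the highest acinar levels. It was 9.23, 9.45 and 9.36 in control replicates 2, 3 and 5, within the 9.13 to 9.56 of the ECP arrays. Matrix remodelling genes had 0.24 (SE 0.20, 13 of 16 higher), or 0.13 without control replicate 1 or 5, with Mmp12, past the threshold when adjusted over the list alone, and the aggrecanase gene Adamts4 at -0.30. Adipocyte genes had 0.25 (SE 0.14, 14 of 17 higher), or 0.15 without control replicate 5, with Pparg, a regulator of fat cell differentiation, at 0.37, the glucose transporter gene Slc2a4 at 0.32 and the leptin gene Lep at 0.26. Adipoq, which codes for the fat cell hormone adiponectin, was at 7.58 ± 0.78 in the ECP arrays and 6.64 ± 1.08 in the controls, a difference of 0.94 (SE 0.49, limma adjusted p = 0.998), or 0.48 without control replicate 5. The fry adjusted p was 0.885 for each of these lists. Camera with a preset correlation called 8 lists, among them proliferation, type I interferon, smooth muscle, adipocyte and matrix remodelling genes, and with an estimated correlation it called 0.

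**Figure D2:**
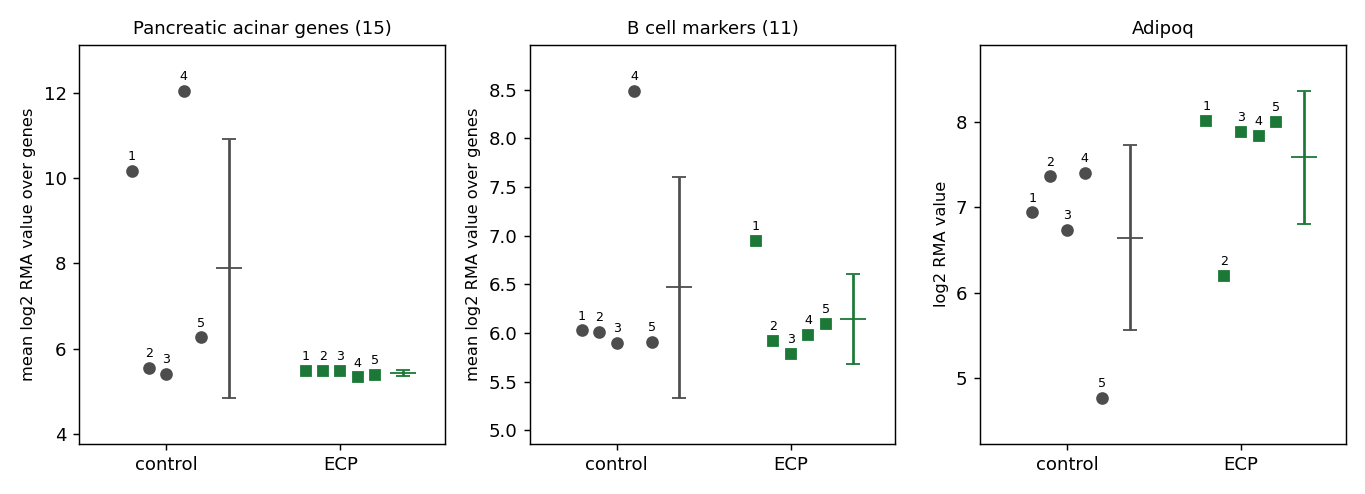
Mean log2 RMA value per array over 15 pancreatic acinar genes and 11 B cell markers, and log2 RMA value of Adipoq (vertical axes, each with its own range not starting at 0), in control arrays (grey circles) and ECP arrays (green squares); numbers are replicate numbers, and horizontal marks with bars are mean ± SD (n = 5). Control replicates 1 and 4 lay at 10.2 and 12.1 in acinar genes, control replicate 4 at 8.49 in B cell markers, and control replicate 5 at 4.77 in Adipoq.

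Across all genes the arrays did not separate by group. The first principal component held 37.1% of the variance and the second 20.9%. Pancreatic genes such as Ctrb1 and Amy2a5 led both, and control replicate 4 lay at 49.6 on the first and control replicate 1 at 35.5 on the second. Group means on the first 4 components did not differ after adjustment (exact permutation p = 0.286, 0.325, 0.0397 and 0.603, smallest adjusted p = 0.159).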

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

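The tests on pancreatic transcripts, on mitosis against replication genes and on muscle were chosen after the values had been seen, and those on B cells, on Adipoq, on pancreatic tissue as a source of the proliferation difference and on other splits before their results. The test on pancreatic tissue as a source used the acinar list, which was itself put together after its values were seen. In 19 of 180 groups of 5 arrays 1 array lay apart from the others, with a gap to its neighbour above 0.71 of the group's range, and chance alone gives about 9. Control replicate 4 accounts for 6 of them. It was high in B cell markers (8.49, next 6.03), Cd79a (9.40, next 6.59), Blk (8.34, next 6.42) and T cell and NK cell markers (6.67, next 5.74), and low in goblet cell and mucus genes (10.64, next 11.02) and Muc2 (13.24, next 13.49). ECP replicate 1 was high in B cell markers (6.94, next 6.10), Ccl22 (7.51, next 6.72) and the first principal component (3.31, next -8.41), and low in Mep1a (10.06, next 10.47) and Muc2 (13.39, next 13.50). ECP replicate 2 was low in adipocyte genes (7.04, next 7.49), Adipoq (6.20, next 7.83) and Lep (4.48, next 5.07), and control replicate 5 in adipocyte genes (6.79, next 7.26) and Adipoq (4.77, next 6.73). Single arrays apart were control replicate 1 in Ifit1 (6.64, next 6.90), control replicate 2 in Ptpro (6.52, next 5.97) and ECP replicate 5 in Reg3g (12.56, next 12.00).

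Adipoq varied with other fat cell genes. Across the 10 arrays its level followed the mean of Car3, Retn, Cidec, Plin1 and Lep (Pearson r = 0.956, permutation p = 6.0e-05; Spearman rho = 0.903, permutation p = 0.00085; 1 relation computed), and r was 0.867 without the 2 arrays farthest from the median of that mean. With these genes as a covariate the Adipoq difference between the groups went from 0.94 to 0.0383 (SE 0.25). A candidate explanation is a varying amount of fat attached to the sampled colon. An effect of the treatment on the amount of fat stays open, since the test does not separate it from dissection.

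Acinar genes were high in control replicates 1 and 4, and their rises over the ECP mean correlated between these arrays across 18 acinar genes, the 3 left-off genes put back (r = 0.953; genes are not independent replicates). In 16 of the 18 both arrays lay above every ECP array, with Ctrb1 at 12.1 and 13.6 and Amy2a5 at 12.6 and 13.3, and the islet gene Ins2 was higher by 1.02 and 2.13, while the islet gene Iapp was at 3.77 and 4.73 against 3.84 in the ECP arrays. The exceptions were Sycn in control replicate 1 and Spink1 in both, which are 2 of the 4 acinar genes above the array median in the ECP arrays (9.67 and 11.47). Pancreatic tissue in the sampled pieces may be the source, but the test, run on genes picked mostly for this pattern, leaves it undecided. The acinar level gave an exact permutation p of 0.0476 between the groups. Its genes were chosen after their values were seen, so that p decides nothing. Control replicate 3 lay within the ECP range and control replicate 2 just above it, so the large rise was not shared by every control array. An effect of ECP was not told apart from pancreatic tissue by these tests.

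Proliferation genes were lower in the ECP arrays, with a mean difference of -0.34 (SE 0.06), which was -0.324 (SE 0.06) with the B cell level and -0.262 (SE 0.05) with the acinar level as a covariate, which argues against either as the whole source. Both corrections ended the call (limma fry adjusted p = 0.0527 and 0.0581, before adjustment 0.00107 and 0.00193), with a smaller difference and 1 residual degree of freedom fewer. Of 100 splits of the arrays, out of 126, 2, the real one among them, gave as many lists past the threshold (real 1, highest of the others 1). Also 2 gave a smallest fry p over all lists as low (real 0.000449, lowest of the others 0.000174). Both shares are under 0.05, the limit set beforehand, which argues against chance as the source of the count of lists. Chance is not excluded, since another split did as well and not all splits were run. For this list, already seen to pass, 1 split, the real one, gave so small a p (next 0.00429). The count of genes (real 0, highest of the others 0, reached by 100 of 100) decides nothing. A larger share of muscle would lower epithelial genes alike, but epithelial junction and keratin genes differed by 0.0274 (SE 0.06), and the difference was -0.309 with the smooth muscle level as a covariate (adjusted p = 0.116), which argues against muscle as the whole source. An effect of the treatment and fewer cycling cells stay open, and mitosis members were lower by more than replication members (difference of the differences -0.384, SE 0.11, exact permutation p = 0.0238), but this division was made after the values were seen and decides neither.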

How the results depend on the processing

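The alternatives on pancreatic transcripts were chosen after seeing the data; the others were planned. Proliferation genes were lower in 27 of 27 alternatives (mean difference -0.383 to -0.252), with an adjusted p under 0.05 in 11. The other set tests, the trend and robust options and the replicate block cannot change this mean, so their sign was fixed in advance. Every ECP array lay below every control array, so leaving arrays out or weighting them could not change the sign either. The count of 27 is therefore no measure of how firm the direction is. Adjusted p-values ran from 3.97e-28 (camera with a preset correlation of 0.01, against an estimated 0.299) to 0.687 (fry). The lowest from fry was 0.00474, without control replicate 3. Genes past the threshold numbered 7 with genes below the median level left out, 1 with the lowest quartile left out and 1 with trend and robust options, where fewer genes were tested or the spread was moderated differently. They numbered 0 to 1 with single arrays left out and 0 in the other alternatives. Leaving out genes below the median level also took the genes at an unadjusted p under 0.05 to 538 (271 higher, 267 lower). Lists past the threshold numbered 8 with camera's preset correlation and 0 with an estimated correlation (proliferation at -0.342, adjusted p = 0.0822) or the exact permutation test (-0.342, 0.389, the smallest it can give). They numbered 0 with the smooth muscle level (-0.309, 0.116), the B cell level (-0.324, 0.0527) or the acinar level (-0.262, 0.0581) as a covariate, without control replicates 1 and 4 (-0.277, 0.105) and without control replicates 1, 4 and 5 (-0.252, 0.687). With single arrays left out they numbered 0 to 1 (-0.383 to -0.303, 0.00474 to 0.117). With fewer arrays or a further term the residual degrees of freedom fall, which raises p at a like difference. Components past the threshold numbered 0 in the 19 alternatives run on them (scaling, filters, probe sets and arrays left out).

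The replicate numbers gave no sign of pairing the arrays. In 0 of 5 pairs of one number did deviations correlate above 0.1 (-0.244 to 0.0761), and 0 arrays correlated best with their own number. A small shared effect could be missed, since these deviations run over all genes and pancreatic genes led the first and second components. With the replicate number as a block 0 genes and 0 lists passed (proliferation -0.342, adjusted p = 0.0713).

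Differences that changed sign were all short of the threshold, and the cause was not tested except where an array was left out. With single arrays left out the ranges were -0.249 to 0.240 for neutrophil markers, -0.523 to 0.182 for B cell markers, -0.165 to 0.107 for T cell and NK cell markers, -0.0362 to 0.0926 for goblet genes, -0.0635 to 0.268 for interferon-gamma genes, -0.0579 to 0.246 for monocyte and macrophage markers, -0.0277 to 0.152 for regulatory T cell genes, -0.0728 to 0.147 for antimicrobial genes, -0.554 to 0.413 for S100a8, -0.843 to 0.0182 for Cd79a, -0.104 to 0.808 for Lcn2, -0.0246 to 0.0589 for Muc2 and -0.0107 to 0.204 for Muc4. Array weights gave 0.141 for neutrophil markers and 0.400 for S100a8. The smooth muscle covariate gave 0.218 for neutrophil markers, 0.952 for S100a8, -0.0186 for goblet genes and -0.00396 for Muc2. The B cell covariate gave 0.123, 0.238, -0.00583 and -0.00481 for these, and 0.0362 for T cell and NK cell markers. The acinar covariate gave 0.438 for neutrophil, 0.399 for B cell and 0.161 for T cell and NK cell markers, 1.13 for S100a8, 0.289 for Cd79a, 0.141 for Blk, -0.0854 for goblet genes, -0.0531 for Muc2 and -0.0661 for Muc4. Without control replicates 1 and 4 the values were 0.356 for neutrophil, 0.203 for B cell and 0.0844 for T cell and NK cell markers, 1.05 for S100a8, 0.0557 for Cd79a, -0.0556 for goblet genes, -0.0328 for Muc2 and -0.0266 for Muc4. Without control replicates 1, 4 and 5 they were 0.175, 0.188, 0.0669, 0.695, 0.131, -0.0304 and -0.0235 for the first 7 of these. Regulatory T cell genes were at -0.0264 with genes below the median level left out. Signal over background could not be judged, since detection calls were not analysed here.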

Other observations

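Many replication-dependent histone genes, whose transcripts build up in S phase, had lower values in the ECP arrays. They were gathered by symbol after H2bc15 and H2bc7, which are among them, had been seen among the smallest p-values, so their values are given without a test. Of 54 such genes 52 were lower and 2 higher, and their mean level was 9.41 ± 0.03 (SD, n = 5) in the ECP arrays and 9.68 ± 0.12 (SD, n = 5) in the controls. Many of these genes are near-identical in sequence, so their probe sets are not independent of each other. Among replication members of the proliferation list, Tyms, an enzyme of thymidylate synthesis, differed by -0.24 (SE 0.07) and the helicase subunit gene Mcm5 by -0.30 (SE 0.10), while Pcna, the sliding clamp of DNA polymerase, differed by 0.06 (SE 0.07) and Mcm6 by 0.00 (SE 0.10). The replication members as a group were at 8.46 ± 0.13 and 8.56 ± 0.20 (SD, n = 5), and the mitosis members at 7.83 ± 0.11 and 8.31 ± 0.08 (SD, n = 5), a division made after the values were seen.

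The 31 lists not described singly had mean differences from -0.10 to 0.26, and the smallest fry adjusted p among them was 0.885. The largest difference, 0.26, was that of 19 PPARG and xenobiotic metabolism genes. Their level was lowest in control replicate 4, at 7.95, against 8.65 to 9.01 in the other controls and 8.51 to 9.14 in the ECP arrays. For TNF and NF-kB response genes (mean 0.01, median -0.01, test direction down), MHC class II genes (mean -0.04, median -0.03, test direction up), unfolded protein response genes (mean -0.02, median 0.04, test direction down) and tuft cell markers (mean 0.03, median -0.02, test direction up), the mean, median and test differed in sign, as they did for mitochondrial respiratory chain genes, whose mean and median lay close to 0.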
